A study of Drosophila melanogaster with 12 samples.

How the data were processed

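The study profiled 2 linker histones of the fruit fly Drosophila melanogaster by chromatin immunoprecipitation and sequencing (ChIP-seq) in S2 cells, an established line derived from late embryos. dBigH1 is the linker histone of the early embryo and the germline, and H1 is the somatic linker histone. The 12 samples form 6 groups of 2 replicates. Control (wild-type) S2 cells and cells labelled as induced to express wild-type dBigH1 were each profiled with a polyclonal antibody against dBigH1, with a polyclonal antibody against H1, and as input. The label of the induced cells gives a 1 mM induction, and the treatment protocol names copper sulphate for 24 h. That protocol is worded identically for every sample, so the labels leave open whether control cells also received copper. All 12 sample descriptions share the same run prefix ahead of the index sequence, and no batch or date is given.

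Peak lists were analysed for the 8 immunoprecipitated libraries, 1 list per library. The 4 inputs were not analysed here. Per the submitters' processing notes, the tools included Bowtie 0.12.5 and MACS 1.4.2, and the genome build was dm3 (Release 5). These notes do not state their settings or whether the inputs served as the peak caller's control. The scaffold names in the lists (2LHet, U, Uextra and the like) belong to that release. Each deposited list gives the chromosome, start, end, a name written by MACS and a score per peak. The score is the authors' value. No list holds a score below 50. In peak files of this MACS version the column is the negative log10 of the caller's p-value times 10, so 50 stands for a caller threshold of 1e-05. It was used only to rank or filter peaks within a list. The lists hold no read counts, so the sequencing depth behind each peak is unknown, and a difference in the number of peaks between libraries can come from depth as well as from occupancy. A peak caller scores local enrichment over background, so a protein spread evenly along chromosomes gives few peaks.

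From these lists, the number of peaks, the covered length and the peak width were computed per library with Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1. Induced and control libraries were compared by the difference of mean log2 values with an exact two-sided permutation test. With 2 libraries against 2 this test has 6 arrangements and cannot give a p below 0.333. The difference between the 2 antibodies was tested by permuting the condition labels within each antibody (36 arrangements, smallest p 0.0556). For each antibody, the peaks of its 4 libraries were merged into regions where they overlapped by 1 bp or more, and a library was counted as holding a region if any of its peaks overlapped it. Regions held by both libraries of 1 condition and by neither of the other were counted, and the same count was made for the other 2 ways of splitting the 4 libraries into pairs. Single regions were not tested, because no test of 2 libraries against 2 by permutation can pass 0.05.

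Overlap between lists was given as the share of peaks overlapping by 1 bp or more with its exact (Clopper-Pearson) 95% binomial interval, which covers counting error only. It was set beside 1000 shuffles of the peaks within their chromosomes, and beside 1000 local shifts in which each peak was moved by 10 to 100 kb. The local shifts were chosen after seeing the data, because peaks gathered in stretches of several Mb. Chromosome ends were taken as the highest peak end in any list. Shares of chromosome classes were compared with the same permutation test and Benjamini-Hochberg adjustment over 8 classes: 2L, 2R, 3L, 3R, X, 4, the Het scaffolds, and U with Uextra. Region classes were compared across chromosomes with Fisher's exact test and the same adjustment, although regions are not independent replicates. Peaks were also counted in 1 Mb windows by their midpoint, and windows with 5 or more peaks in both induced dBigH1 lists were called blocks, a choice made after seeing the data.

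The designs, the rule for named regions and the alternatives listed next were fixed before the data were examined. That rule takes, for each antibody and each of 3 region classes, the 10 regions on 2L, 2R, 3L, 3R, X and 4 with the lowest mean rank of the score within the lists that hold them. The alternatives were a score of 100 or more, the named chromosomes only, joining peaks closer than 1000 bp, a stricter overlap, lists of equal length, each replicate left out (for peak number, covered length, region counts and the difference between antibodies), and a replicate block. The region and overlap code was tested on simulated lists: for both antibodies it placed 800 of 800 simulated regions in their class and found 300 of 300 planted overlaps. The simulated regions were kept well apart, so this does not cover dense or adjoining peaks such as those of the H1 lists. Planned results on gene features and gene lists, with the genes they would have named, were not computed, because the gene table used here follows Release 6 and coordinates were not converted between releases. All positions below are dm3 coordinates, counted from 1.

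The labels number the replicates 1 and 2 in every group without saying whether a number marks a shared culture. Across regions, the difference between replicates 1 and 2 in control cells was nearly uncorrelated with that in induced cells. Pearson's r was 0.0025 over 1263 dBigH1 regions and 0.0066 over 6653 H1 regions, and the samples were treated as unpaired. These values do not exclude structure by replicate number. Over 1 Mb windows, H1 lists of the same number had an r of 0.965 and 0.983 between conditions, against 0.931 and 0.946 between replicates of a condition. The dBigH1 lists went the other way, with 0.321 and 0.701 against 0.719 and 0.851. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries.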

Results

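The peak lists showed where the antibodies against dBigH1 and H1 gave local enrichment, with 2 libraries per antibody and condition. The conditions were control S2 cells and cells labelled as induced to express dBigH1 (induced cells). Whether control cells contain dBigH1 was not measured here, so dBigH1 peaks below means peaks called with that antibody. The dBigH1 lists held 599 and 719 peaks in control cells and 196 and 238 in induced cells. H1 lists were longer, with 3814 and 5072 peaks in control and 3545 and 5182 in induced cells. In each of the 4 groups the replicate 2 list was the longer. Covered length ranged from 0.611 Mb in the first induced dBigH1 library to 14.9 Mb in the second induced H1 library.

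The first comparison asked how the dBigH1 signal differed between control and induced cells. Lists from induced cells were shorter, and their peaks were broader and lower in score. Control libraries held 659 ± 84.9 peaks and induced libraries 217 ± 29.7 (mean ± SD, n = 2), a 3.04-fold lower number in induced cells (log2 ratio -1.60). Covered length differed less, at 1.34 ± 0.0872 Mb in control and 0.716 ± 0.149 Mb in induced cells, because mean peak width was 2046 ± 131 bp in control and 3284 ± 237 bp in induced cells. In each of these 3 measures the control and induced libraries did not overlap, which gave an exact two-sided permutation p of 0.333, the smallest that 2 against 2 libraries allow. Control scores reached 3100, a value tied by 5 peaks in each control list that may be a ceiling, whereas the highest induced scores were 222 and 768. Peaks with a score of 100 or more made up 44.1% and 37.0% of the control lists and 10.2% and 16% of the induced lists. Restricting all lists to such peaks moved the log2 ratio of peak number to -3.26.

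**Figure D1:**
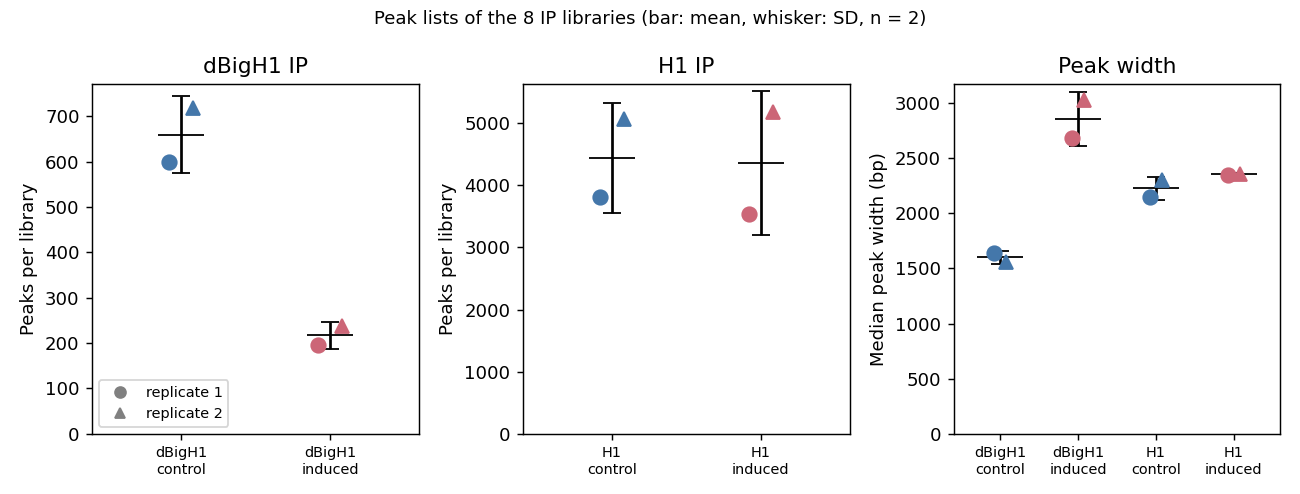
Number of peaks per library for the dBigH1 and H1 immunoprecipitations and median peak width in bp, with 1 point per library (circle, replicate 1; triangle, replicate 2), the mean as a bar and the SD as a whisker (n = 2). Induced dBigH1 libraries (196 and 238 peaks) lie below control dBigH1 libraries (599 and 719), while H1 lists of the 2 conditions overlap in length.

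The positions of dBigH1 peaks also differed between conditions. Of 1263 merged dBigH1 regions, 344 were held by both control libraries and no induced library, 31 by both induced libraries and no control library, and 4 by all 4 libraries. The other 2 ways of pairing the 4 libraries gave 4 and 22 regions (by replicate number) and 8 and 13 regions (crossed). Requiring a score of 100 or more left 167 control and 3 induced regions, and lists cut to equal length gave 127 and 39. Control replicates shared 364 of the 599 peaks of the shorter list (60.8%, 95% interval 56.7 to 64.7), against 2.37% in shuffled lists. Induced replicates shared 45 of 196 (23.0%, 17.3 to 29.5), against 1.96% in shuffled lists and 9.47% after local shifts. Between conditions, 8.67% (replicate 1) and 16.8% (replicate 2) of the peaks of the shorter, induced list overlapped a control peak, above the 2.04 to 7.16% and 6.30 to 13.4% that local shifts gave.

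The top control regions lay mostly on X. The 3 first-ranked regions absent from induced lists were X 2683524 to 2687731, X 2689529 to 2692769 and X 5788425 to 5796300. They were tied, each with a score of 3100 in both control libraries. Next came 3R 21068868 to 21071196 (scores 3100 and 2445), X 5589406 to 5591862, X 13533989 to 13536108, 2R 19599563 to 19601781, 3R 24705376 to 24706839, X 13731504 to 13733716 and 2L 6612169 to 6613312. These 10 regions were 1.14 to 7.88 kb wide. Induced regions absent from control lists were led by 2L 16192178 to 16198104 (scores 103 and 127), 3L 3589910 to 3593908 (97.8 and 126) and 3L 3004660 to 3009121 (100.85 and 99.15). The other 7 lay at 3L 6092030, 3L 5436093, 2L 18346583, 3L 5958678, 3L 4521724, 2L 14724576 and 3L 2079083, so that all 10 were on 2L or 3L. Median width was 1601 bp for the 344 control regions and 3424 bp for the 31 induced regions. The 4 regions in all libraries were 2R 9372718 to 9374361, which ranked 7 and 1 in the control lists (the latter shared by the 5 peaks with a score of 3100) and 107 and 1 in the induced lists, and 2L 15840728 to 15848679, 2L 18286751 to 18291457 and 2L 17847206 to 17856622.

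The next comparison asked whether dBigH1 was called where H1 was called. In induced cells most dBigH1 peaks overlapped an H1 peak of the same condition and replicate number, and in control cells few did. The shares were 56.1% (95% interval 48.9 to 63.2) and 58.4% (51.9 to 64.7) in induced libraries, and 15.9% (13 to 19) and 23.5% (20.4 to 26.8) in control libraries. Induced libraries averaged 57.3% ± 1.61 and control libraries 19.7% ± 5.41 (SD, n = 2), a difference of 37.6 percentage points that was larger than either spread, at an exact two-sided permutation p of 0.333, the smallest possible. Local shifts of the peaks gave 34.1% and 40.1% on average in induced cells, and their central 95% ranges ended at 39.8% and 45.8%, so the induced overlap exceeded that of nearby positions. In control cells the local shifts averaged 14.1% and 20.7%. The first control library lay within their range (11.7 to 16.5%), and the second lay just above its range (18.1 to 23.4%). Shifted peaks keep their width and neighbourhood, and they too overlapped H1 more often in induced than in control cells. Part of the 37.6 points therefore goes with width and neighbourhood and not with exact position. Observed shares were 1.65 and 1.46 times the shifted means in induced cells and 1.13 and 1.14 times in control cells.

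Control dBigH1 peaks differed by score in their overlap with H1. When each control list was divided by score into 4 parts of equal size, 1.33% and 3.33% of peaks in the highest part overlapped H1, and 30.2% and 42.5% in the lowest. No local shifts were made for these parts. Control peaks with a score of 100 or more lay on X in 26.9% and 26.3% of cases and weaker ones in 12.8% and 9.93%. H1 peaks are few on X, so chromosome position may account for part of this difference, which was not tested. Control peaks that recurred in the other control replicate overlapped H1 in 6.87% and 8.52% of cases, and those that did not recur in 29.8% and 38.9%. The 344 regions held only by both control libraries overlapped an H1 peak of either control library in 22 cases (6.40%, 4.05 to 9.52), below the 13.1 to 19.8% that local shifts gave. By contrast, 25 of the 31 regions held only by both induced libraries overlapped an induced H1 peak (80.6%, 62.5 to 92.5), against 41.9 to 71.0% for local shifts. The same 31 regions overlapped control H1 peaks in 23 cases (74.2%), at the upper end of the local shifts (45.2 to 74.2%).

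**Figure D2:**
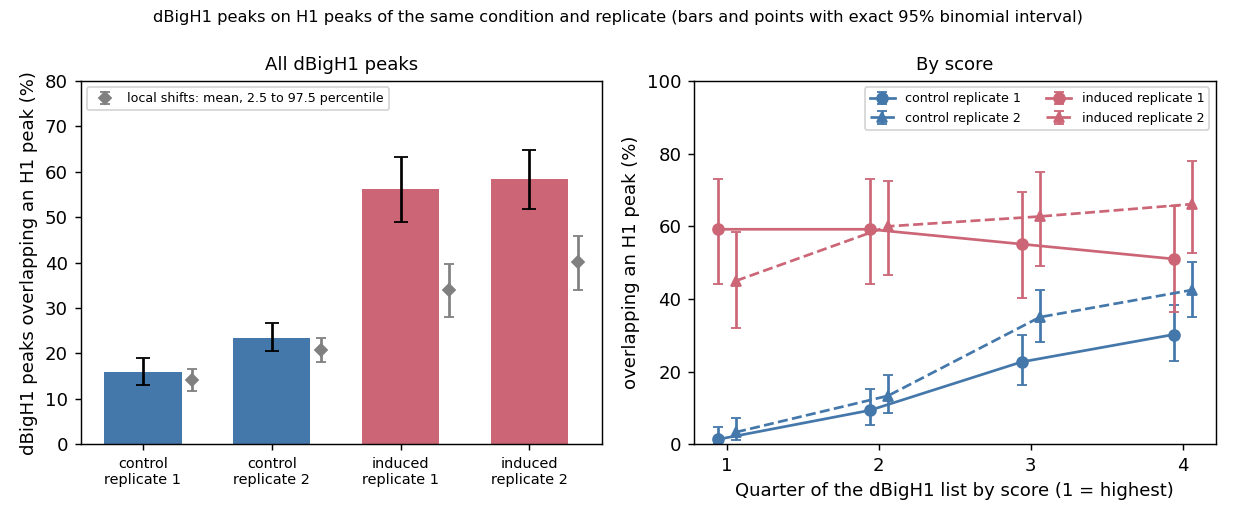
Left, the share of dBigH1 peaks (%) overlapping an H1 peak of the same condition and replicate number in each dBigH1 library, with grey diamonds for the mean and range of 1000 local shifts; right, the same share for 4 equal parts of each dBigH1 list ranked by score. Whiskers on bars and coloured points are exact 95% binomial intervals; the control share climbs from 1.33% and 3.33% in the highest part to 30.2% and 42.5% in the lowest, and the induced libraries lie between 45% and 66.1% in every part.

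For H1, the comparison asked whether its own distribution differed between control and induced cells. The number of H1 peaks was 4443 ± 890 in control and 4364 ± 1158 in induced cells (SD, n = 2), a log2 ratio of -0.04 with an exact permutation p of 1. The ratio was -0.11 for replicate 1 and 0.03 for replicate 2. Covered length was 12.2 ± 2.72 Mb and 12.4 ± 3.46 Mb (exact permutation p = 1). Of 6653 merged H1 regions, 1441 (21.7%) were held by all 4 libraries, 229 by both control and no induced library, and 204 by both induced and no control library. The crossed pairing of libraries gave similar counts of 223 and 171, and the pairing by replicate number gave 78 and 595. Replicates shared 73.2% of the shorter list in control and 76.9% in induced cells, and between conditions 61.6% and 71.8% of peaks were shared within a replicate number. The log2 ratio of peak number for dBigH1 minus that for H1 was -1.57, and -1.63 and -1.51 without replicate 1 and without replicate 2. The exact permutation p was 0.222 over 36 arrangements. The smallest p this test allows is 0.0556, so it could not establish a difference between the antibodies.

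H1 regions found in all 4 libraries and ranked highest lay on 2L, with 2L 16199637 to 16218627, 2L 18299713 to 18309369 and 2L 22098167 to 22102790 in the lead. The next were 2L 15829817, 2L 16067606, 2L 16146217, 2L 15799396, 2R 6264509, 2R 1350135 and 3L 18473531 (start positions). The leading region of the induced libraries alone was 2L 14964055 to 14972788, which ranked 4 and 1 in the induced lists with scores of 867 and 1508. Its nearest control H1 peaks were 0.257 and 0.323 kb away. The next induced region, 3R 15377057 to 15380136, had a mean rank of only 374. Regions of the control libraries alone were led by 2L 16019732 to 16027531, 2L 15409213 to 15419597 and 3L 4765839 to 4773858, with mean ranks of 27, 45.5 and 48. Induced H1 peaks came within 0.023 and 0.104 kb of 2L 15409213 to 15419597, whereas the nearest to 3L 4765839 to 4773858 were 55.6 and 56.8 kb away.

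Chromosomes differed most in the dBigH1 lists. X held 17.5% ± 2.15 of control dBigH1 peaks and 1.14% ± 0.17 of induced ones (SD, n = 2), and 3L held 17.0% ± 0.921 and 38% ± 2.59. 2L held 26.1% ± 1.79 and 36% ± 3.23, and 2R held 11.9% ± 1.75 and 4.77% ± 0.976. Each of these contrasts separated the libraries by condition (exact permutation p = 0.333, the smallest possible; adjusted p = 0.381 over 8 classes). H1 was rarely called on X in either condition, with 1.60% ± 0.11 of control and 1.25% ± 0.0565 of induced peaks. Per Mb, X carried 0.0749 and 0.0821 times as many H1 peaks as the large autosome arms in control cells and 0.0606 and 0.0652 times in induced cells. The same ratio was 1.16 and 0.924 for dBigH1 in control cells and 0.0466 and 0.0573 in induced cells, where it rests on 2 and 3 X peaks. On chromosome 4, H1 had 2 peaks in the first control library and 0 in the other 3 libraries.

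**Figure D3:**
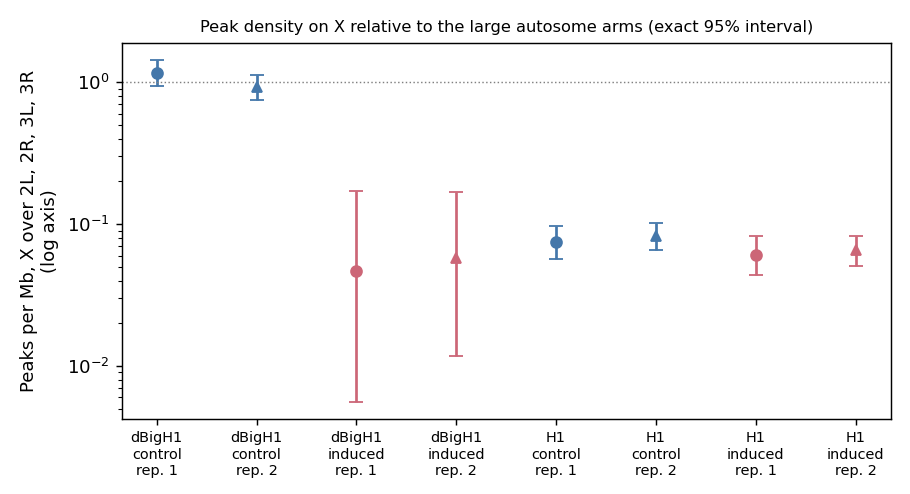
Peaks per Mb on X divided by peaks per Mb on 2L, 2R, 3L and 3R together, on a log axis, for each of the 8 libraries with its exact 95% interval from the peak counts. Control dBigH1 libraries lie near 1 (1.16 and 0.924), and induced dBigH1 and all H1 libraries lie below 0.1.

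The Het scaffolds, which hold assembled pericentric sequence, carried 5.66% ± 0.259 of H1 peaks in control and 7.52% ± 0.386 in induced cells (SD, n = 2), with every induced library above every control library (exact permutation p = 0.333; adjusted p = 0.889). Among H1 regions held by 1 condition only, 18 of 204 induced regions and 3 of 229 control regions lay on these scaffolds (8.82% and 1.31%; Fisher's exact test, adjusted p = 0.0019). The crossed pairing of libraries gave 14 of 223 and 6 of 171 (Fisher's exact test, adjusted p = 0.442). That pairing passed the same exact test on 3L (adjusted p = 0.0493), as the pairing by replicate number did on 2L (0.0016), so p-values over regions are too small as a measure of condition. For dBigH1, 14 of 31 induced and 53 of 344 control regions lay on 3L (adjusted p = 0.0017), and 1 and 88 on X (adjusted p = 0.0131, Fisher's exact tests).

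Along the arms, H1 peaks alternated between dense and nearly empty stretches that were shared by all 4 H1 libraries. The 1 Mb window at 17 Mb of 2L held between 157 and 182 H1 peaks in each library. In 12 of the 98 windows of the large autosome arms, every H1 library had 5 peaks or fewer. These windows lay at 3 to 4, 5 to 8 and 20 to 21 Mb of 2L, 20 to 22 Mb of 2R, and 7 to 10, 11 to 12 and 15 to 16 Mb of 3L. The last 2R window holds little sequence, as the highest peak end on 2R was at 21.1 Mb, but it was counted in full. Windows at the ends of the other arms also fall short of their full length. Induced dBigH1 libraries had 1 and 0 peaks in these 12 windows, against 2.21 and 2.71 per window elsewhere on these arms. The windows elsewhere include the blocks, which were chosen for many induced dBigH1 peaks and held 95 and 122 of them, so this contrast is enlarged. Control dBigH1 libraries had 50 and 39 peaks there. Their rate in these windows was 0.921 (95% interval 0.672 to 1.24) and 0.543 (0.381 to 0.752) times that elsewhere.

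**Figure D4:**
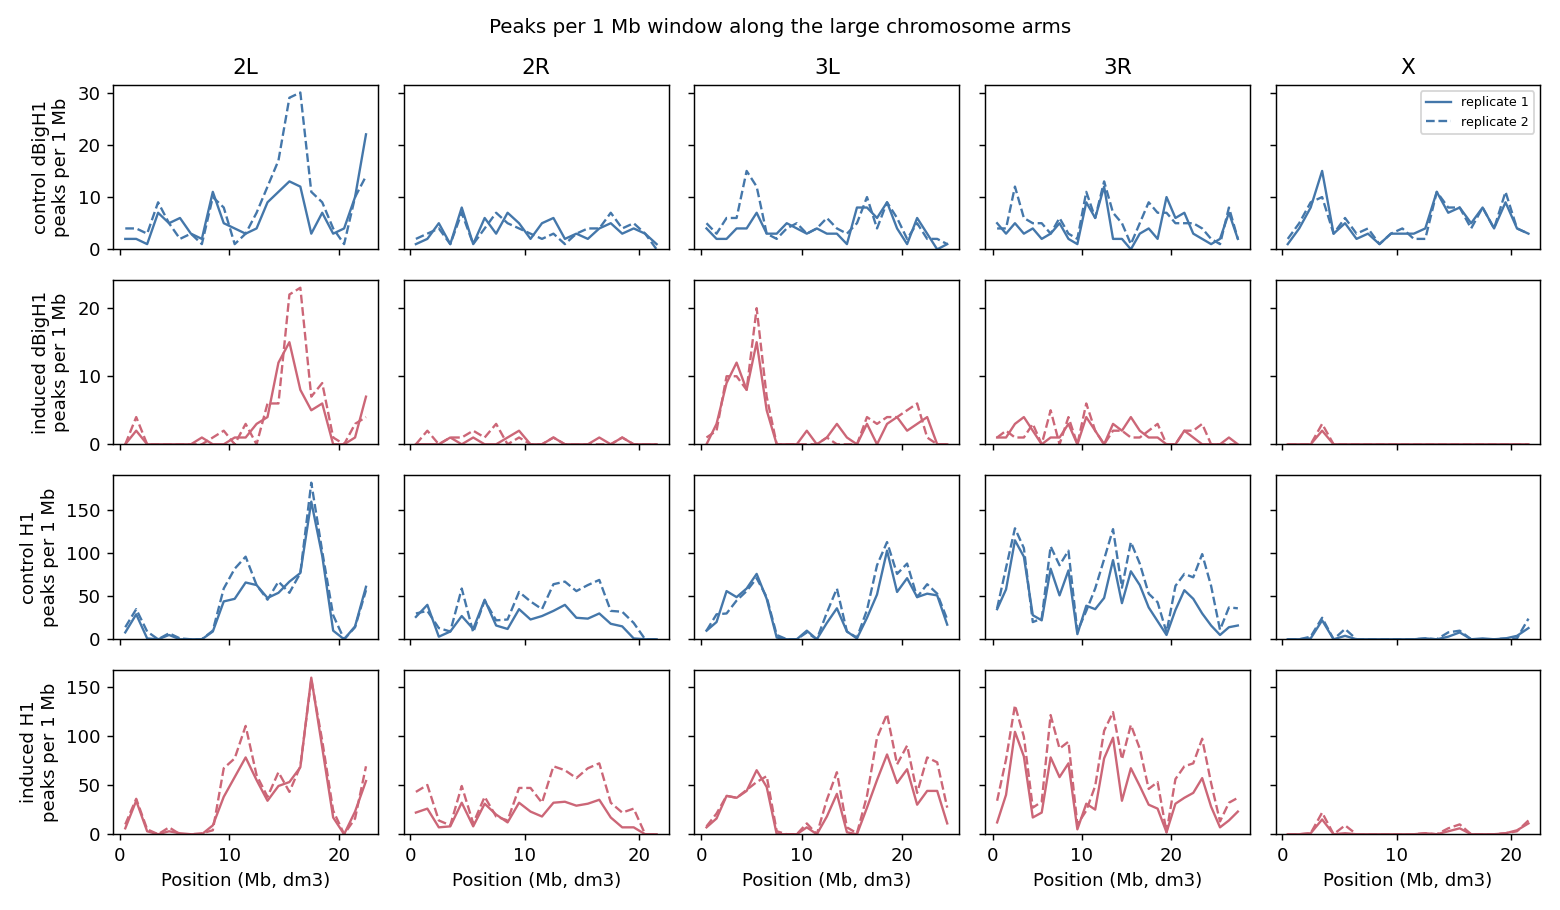
Peaks per 1 Mb window (vertical axis, number of peaks) against position in Mb (dm3) on 2L, 2R, 3L, 3R and X, with 1 row per antibody and condition and 1 line per library (solid, replicate 1; dashed, replicate 2). H1 peaks are dense around 17 Mb of 2L and sparse on X; induced dBigH1 peaks gather at 14 to 19 Mb of 2L and 2 to 7 Mb of 3L.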

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

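Libraries were compared by permutation with 2 per group. No comparison by this kind of test could pass a threshold of 0.05, so the alternatives bear on size and direction only. Of 92 alternative values for the comparisons, 70 counted as unchanged, 19 moved and 3 changed direction. All 3 concerned the H1 totals, which hardly differed between conditions. The 70 include the values of the replicate block, which equal the main values by construction. They also include the H1 overlap with only recurring control peaks kept, whose direction was fixed in advance. Region counts and replicate overlaps were judged by size, and all 19 that moved were of these kinds. Log2 ratios, the difference between antibodies, the overlap of dBigH1 with H1 and chromosome shares were judged by direction only, whatever their size. The dBigH1 log2 ratio of peak number thus counted as unchanged at -3.26 (score of 100 or more) against -1.60 in the main setting. The H1 log2 ratio of covered length was 0.021 and became -0.0069 on the named chromosomes; it ranged from -0.038 to 0.079 with each replicate left out, and that of H1 peak number from -0.11 to 0.031. A score of 100 or more gave 167 dBigH1 regions for both control libraries and 3 for both induced ones, 122 control H1 regions, and replicate overlaps of 15% (induced dBigH1), 62.9% (control H1) and 73.2% (induced H1). Asking for 50% of a peak to be covered gave H1 replicate overlaps of 68.9% (control) and 73.6% (induced). Equal list length gave 127 control dBigH1 regions, by construction fewer than from the full lists, and joining peaks closer than 1000 bp gave 135 control and 120 induced H1 regions. With each replicate left out, a region needs only 1 library against 1, so the counts were far higher by construction: 582 to 679 and 179 to 198 dBigH1 regions in control and induced cells, and 1428 to 1602 and 1363 to 1690 H1 regions. The cause of the other movements was not tested.

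The dBigH1 log2 ratio of peak number stayed negative in every alternative, between -3.26 and -1.52, and its covered length ratio between -2.11 and -0.77. The overlap of dBigH1 with H1 stayed higher in induced than in control cells by 33.8 to 41.4 percentage points. Keeping only recurring control peaks gave 49.6. That widening was fixed in advance, because recurring control peaks overlap H1 less and the induced lists were left whole. This setting, and leaving out a replicate here and for the chromosome shares, were chosen after seeing the data. With the replicate number as a block, the log2 ratios of peak number were -1.60 for dBigH1 and -0.04 for H1. Their exact sign-flip p was 0.5 and 1. The log2 ratios of covered length were -0.92 and 0.021, and the difference between antibodies was -1.57. The block leaves these values as in the main setting by construction, so it cannot test their direction. Of the 10 named dBigH1 regions of induced cells, 1 kept its class at a score of 100 or more, against 10 of 10 for control cells. The 4 dBigH1 regions held by all 4 libraries kept that class in 0 of 4 cases at a score of 100 or more, in 1 at equal list length and in 2 where 50% of the region had to be covered. Results on gene features and gene lists were not run. No replicate could be left out of the replicate overlaps. The depth of the libraries is unknown, so the absence of a peak is not evidence that the protein was absent.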

Other observations

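Recurrence between replicates followed the score in most lists. In control dBigH1 lists, 90.7% and 89.4% of the highest-scoring of 4 equal parts recurred in the other replicate and 36.2% and 22.9% of the lowest. In induced dBigH1 lists the highest part recurred in 38.8% and 26.7% of cases. At the scale of 1 Mb windows the 2 induced lists resembled each other more closely, with Pearson's r of 0.851 and Spearman's rho of 0.759 across 122 windows, which are not independent replicates. The second control dBigH1 list resembled the induced ones at this scale by Pearson's r (0.613 and 0.701) but less by rho (0.362 and 0.420), and the first list less by both (r of 0.321 and 0.327). The H1 lists had a rho of 0.578 to 0.731 and an r of 0.309 to 0.575 with the induced dBigH1 lists, so the order of the lists depends on the measure.

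H1 regions of high rank (a mean rank of 150 or less) that were held by 1 condition only numbered 6, against 4 and 1 in the other pairings of the 4 libraries, so chance alone would put the true pairing first in 1 of 3 cases. All 6 lay at 14 to 19 Mb of 2L or 2 to 7 Mb of 3L, as did the 4 of the pairing by replicate number. The region at 2L 14964055 to 14972788, the highest-scoring H1 peak of the second induced list, carried dBigH1 peaks in both control libraries and in 1 induced library.

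All tests in this part were chosen after the result, or part of it, had been seen, except 3: the rate of calls in the blocks, the overlap of block peaks with H1 beside local shifts, and the X share of weak control peaks. The local shifts themselves and the H1-poor windows were also chosen after seeing the data.

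Control cells gave more dBigH1 peaks than cells labelled as induced to make the protein, at other places. Of the regions held by both control libraries, 9.89% overlapped a control H1 peak (7.02 to 13.4). This argues against sites called with both antibodies as the main source. It does not exclude unspecific sites that the H1 lists miss, because the H1 antibody has its own target. A loss of peaks in all induced libraries does not account for the difference, since the lower H1 log2 ratio was -0.11. A partial loss of yield would keep the strongest control peaks. Of the highest of 4 parts by score, 0.667% and 1.67% were kept in the induced list. That argues against such a loss, since 90.7% and 89.4% of that part recurred between controls. Of the lowest part, 6.71% and 6.70% were kept. A rule asking for 95% intervals apart in both replicates could not decide between the parts, as the intervals overlap. Fisher's exact test gave p = 0.0054 and 0.0186, peaks not being replicates. Neither rule had local shifts beside it, and strong control peaks lay more often on X, where induced peaks are few. The contrast between the parts is therefore not weighed. A complete failure of the induced immunoprecipitation stays open. Of the induced peaks, 8.67% and 16.8% overlapped a control peak, above the upper ends of the local shifts (7.16% and 13.4%). This excess goes against a complete failure only if background gives no peaks common to both conditions, which was not tested. It also stays open that the antibody may recognise other protein at sharp, H1-poor sites in control cells, that induced dBigH1 may be spread so evenly that few places exceed the local background, or that the 2 conditions are crossed in the labels; read coverage and the inputs would bear on these, and no biological explanation was tested.

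Induced dBigH1 peaks gathered in 2 blocks, 14 to 19 Mb of 2L and 2 to 7 Mb of 3L; since the blocks were chosen on these lists, the gathering was also measured in windows chosen on 1 induced list, which held 53.4% (list 2 in 9.22% of the span) and 56.5% (list 1 in 12.6%) of the peaks of the other. More calls of any kind in the blocks, as a higher copy number in this cell line could give, matches the direction in the other 6 libraries. Their rates in the blocks were 1.47 and 2.83 times those outside for control dBigH1 and 1.81 to 2.93 times for H1. In the windows chosen on induced list 1, the ratio was 11.3 (8.66 to 14.7) for induced list 2, and 1.85 and 2.88 for control dBigH1. In those chosen on list 2 it was 9.02 (6.72 to 12.1) for list 1, and 1.41 and 2.38 for control dBigH1. H1 gave 1.83 to 2.92 over both sets. These other ratios fall short of the induced ones, but how peak numbers scale with copy number was not tested, so the gap does not decide. A short list that keeps only the strongest calls is in line with the top H1 peaks, of which 48.7% and 40.3% fell in the blocks in induced cells when as many were taken as the dBigH1 lists held, but not with the top control dBigH1 peaks (6.22% and 8.90%). Copy number may also underlie the dense and empty H1 stretches and the 12 H1-poor windows, where control dBigH1 had 0.921 and 0.543 times its rate elsewhere; this was not decided, and the use of the inputs in peak calling is not given in the sources used here. Whether induced dBigH1 follows H1 within the blocks stays open: 56.8% and 54.1% of block peaks overlapped H1, above the central 95% range of local shifts in replicate 1 (up to 51.6%) and within it in replicate 2 (up to 55.7%).

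X carried few H1 and induced dBigH1 peaks. Fewer X reads in this line could push X peaks under the threshold and would thin out weak control dBigH1 peaks on X first. Of control peaks with a score under 100, 12.8% and 9.93% lay on X, above the 5% set beforehand (lower bounds 9.45% and 7.34%) but below the 26.9% (21.6 to 32.7) and 26.3% (21.1 to 32.0) of stronger peaks. On X relative to the autosome arms, weak control peaks had 0.438 (0.279 to 0.681) and 0.315 (0.203 to 0.485) times the odds of strong ones. The H1 ratios of 0.0606 to 0.0821 (highest upper bound 0.102) were lower, but they are peaks per Mb over all scores, an unlike measure. Fewer X reads as the whole cause are argued against only under 3 untested conditions. The loss at a given score is the same for both antibodies, strong dBigH1 peaks on X were not lost, and H1 would otherwise be as dense on X as on the autosomes. A contribution of fewer X reads stays open. A biological difference of X chromatin from that of the autosomes stays open as well, and was not tested.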
